A study of Mus musculus with 4 samples.

How the data were processed

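MILI-bound small RNAs were measured in 14-day testes of C57BL/6 mice, in 2 Tdrd9+/- and 2 Tdrd9-/- libraries. Per the labels' protocols, RNA was immunoprecipitated from testis lysate, RNAs of about 28 to 30 nt were eluted from a gel with radioactive markers, and libraries were made with an Illumina small RNA kit. The genome build was mm9, per the submitters' processing notes. The aligner, the mismatches allowed, adapter removal and any filter on reads are not given in the sources used here.

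Per the file headers, the deposited table has 5 columns: sequence, chromosome, start, end and strand. Its values are 1-based genome positions and not read counts or expression values. Each of the 4906138 rows held a different sequence, the length of every sequence equalled end minus start plus 1, and no position was held by more than 1 sequence. Where sequences overlapped on 1 strand or across strands, 0 of 51593534 covered bases disagreed, as in a list of perfect matches. All libraries share the table with no library column, so the depth per library is unknown, and abundant and rare sequences count alike. Each sequence appears at 1 position. Of 1451866 neighbouring pairs in which a sequence is the start of a longer one, all 1451866 shared their 5′ position, as sequences with a single genome match would. Fragments of an abundant RNA are counted once each, so a longer or more deeply sampled transcript adds sequences up to a ceiling.

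The tests planned before the data were examined compared the genotypes by repeat element, gene and 20 kb window with count models, and compared shares per library with permutation tests. None could be run, because the table has neither counts nor libraries, and the repeat lists were not used because no repeat annotation of mm9 was used here. The list was described instead. Named genes and windows follow the part of the planned rule that still applied: the 5 with the most sequences, and Tdrd9. A few genes, 1 of those 5 among them, are not reported here. The 12 gene lists of cell types and pathways were written after the table's format was known and before any match to a gene was made, and their members are named as examples. Other genes named were chosen after their values were seen.

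Sequences were compared with the transcripts of GENCODE release M21 (141767 transcripts) by exact match of the whole sequence in sense and antisense. Only sequences, gene types, coding limits and chromosome names were taken from that annotation, which is built on GRCm38, and no coordinate was converted or mixed with mm9. Sequences of a gene were those matching that gene only. Sense matches in more than 1 gene made up 1.61% of sense-matched sequences. Of the sequences of protein-coding genes, 99.95% lay on the chromosome of the gene. Introns were not told apart from intergenic sequence. Densities are distinct 5′ ends per kb of the longest transcript. For regions, the transcript with the longest coding sequence stood for its gene, and the interval of the pooled ratio came from 500 bootstrap draws over genes. Each gene list was set against 10000 random lists of the same size, drawn from the 200 genes on each side in order of transcript length, with or without a sequence. The percentile describes this list of sequences and tests no condition.

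Opposite-strand overlaps were counted between distinct 5′ ends, and the ratio divides pairs at 10 nt by the mean of the other overlaps from 1 to 20 nt. The matching step was tested on simulated data and found 500 of 500 planted sequences. The overlap step was tested on simulated data with 6000 planted pairs, of which 97.8% were recovered, and gave a ratio of 1.00 with nothing planted. Sequences per Mb divide by the largest listed position of the chromosome in place of its length. Windows were 20 kb, and neighbouring windows with 1000 or more sequences were joined into clusters. Intervals of shares are exact Clopper-Pearson 95% intervals for counting error only, and no replicate error can be had from the pooled list. Alternatives covered sequences of 24 to 31 nt, leaving out structural RNAs, counting 5′ ends in place of sequences, leaving out recurring ends, other window sizes, other rules for several genes and other transcripts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.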

Results

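Small RNAs bound to MILI (Piwil2), the PIWI protein of pre-pachytene and meiotic male germ cells, were recovered by immunoprecipitation from testes of C57BL/6 mice at 14 days post partum. The study had 4 libraries, 2 from heterozygous Tdrd9+/- mice and 2 from Tdrd9-/- mice, and asked how MILI-bound RNAs differ when the helicase TDRD9 is missing. The table used here lists 4906138 distinct sequences with their mm9 positions, pooled over the 4 libraries. It carries no read counts and no library labels, so the depth per library is unknown, no replicate error could be computed and the genotypes were not compared. The pooled list was therefore described in its own right: its size and base profile, the genes and regions it came from, opposite-strand pairing and its clusters. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error over distinct sequences only.

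The MILI-bound sequences had the length and 5′ base of piRNAs. RNAs of about 28 to 30 nt had been eluted from a gel beforehand, so the length is no independent mark of piRNAs. Lengths ran from 18 to 36 nt, with a mean of 27.1 nt (SD 1.31 nt over sequences) and a mode of 27 nt, which held 30.4% of the list. Sequences of 26 to 28 nt made up 77.0%, and the 28 to 30 nt class named in the labels for gel elution made up 37.1%. A 5′ U, the mark of primary piRNAs, was carried by 75.4% of sequences (75.4–75.5%), against 20.7% U on average at positions 11 to 20. The other first bases were A at 10.4%, C at 7.59% and G at 6.54%. A at position 10, the mark of secondary piRNAs made by slicing, was carried by 31.7% of sequences (31.7–31.8%), against 30.7% A on average at positions 11 to 20. Position 10 did not stand out: A was more frequent at positions 3, 4, 5 and 6 (31.9%, 33.3%, 39.4% and 33.5%) and also stood at 31.7% at position 12. Sequences without a 5′ U had A at position 10 in 32.7% of cases (32.7–32.8%) and those with a 5′ U in 31.4% (31.4–31.5%). From 25 to 30 nt the share with a 5′ U went from 72.5% to 82.4% and the share with A at position 10 from 25.3% to 35.7%. The 4906138 sequences shared 3454272 distinct 5′ ends, of which 74.2% had a single sequence and the fullest had 12.

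**Figure D1:**
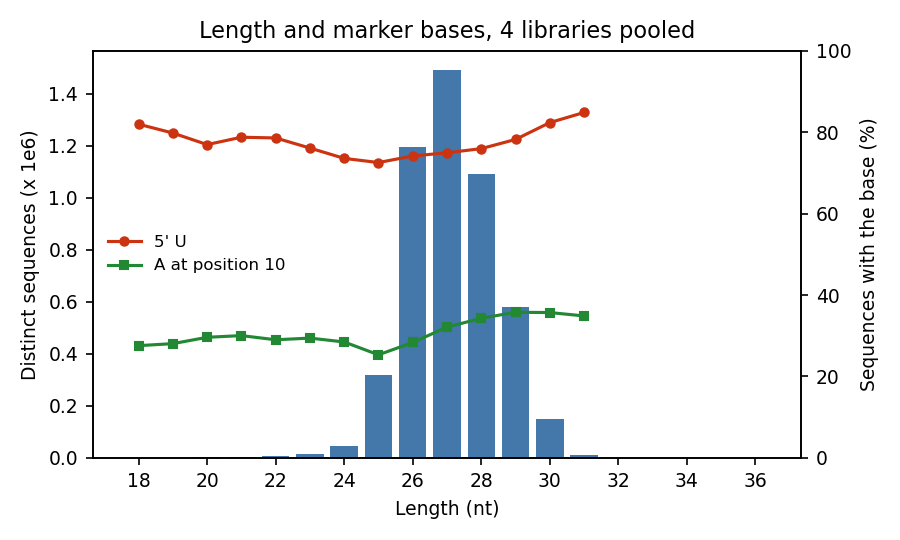
Number of distinct sequences (bars, in units of 1e6, left axis) and share with a 5′ U (circles) or A at position 10 (squares; percent, right axis) by length in nt, 4 libraries pooled, with shares drawn for lengths of 500 or more sequences. The bars peak at 27 nt with 30.4% of the list, and the share with a 5′ U goes from 72.5% at 25 nt to 82.4% at 30 nt.

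Protein-coding messenger RNAs were a main source of the listed sequences. Exact matches to spliced transcripts were found for 53.1% of the list, and 47.6% (47.5–47.6%) was sense to a protein-coding gene. Sense sequences made up 94.5% (94.5–94.6%) of those matched in a single orientation, and 2.81% of the list was antisense only. Long noncoding and unclassified genes held 2.43% in sense, and pseudogenes 0.516%. By annotated gene type, structural RNAs held 0.0600% (2946 sequences) and microRNA hairpins 0.0257% (1259 sequences). The remaining 46.9% of the list had no exact transcript match, which leaves introns, intergenic clusters and repeats together. A 5′ U was carried by 81.6% (81.6–81.7%) of the unmatched sequences, 79.4% (79.2–79.6%) of the antisense-only sequences, 69.2% (69.1–69.3%) of those sense to protein-coding genes and 52.6% (50.8–54.5%) of those sense to structural RNAs. How much U the source sequence of each set holds was not measured. Repeat elements were not analysed here. The list appears to hold only sequences with a single genome match, so RNAs of multi-copy repeats and genes may be missing from it. The shares above are therefore shares of listed distinct sequences and not of all MILI-bound RNA.

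The sequences were spread over many genes and piled up on a few. Of 22445 protein-coding genes searched, 16011 had at least 1 sequence of their own, 5658 had 100 or more and 346 had 1000 or more, with a median of 18. Immunoglobulin and T-cell receptor gene segments were counted among the 22445 and could be drawn into the random lists used below. The 100 fullest genes held 11.5% of the gene sequences. D10Wsu102e stood first with 19012 sequences at 10088 distinct 5′ ends, on the plus strand of chromosome 10 between mm9 positions 82822966 and 82951232. Its annotated transcript is 123179 nt long, of which 122586 nt are 3′ UTR. The 3′ UTR held 98.6% of the ends, at a density per nt 0.336 times that of the coding sequence. Abl2, a tyrosine kinase of the Abelson family, followed with 5739 sequences (chromosome 1, 158488917–158579678, plus strand). The lincRNA Gm49794 had 5362 sequences (chromosome 17, 27491411–27504246, plus strand). Gabpb2, a subunit of the GA-binding protein transcription factor, had 4907 (chromosome 3, 94985780–95021816, minus strand). For each of these 4 genes 100% of the sequences lay on the gene's own chromosome, and antisense sequences numbered 13 for D10Wsu102e, 6 for Abl2, 10 for Gm49794 and 16 for Gabpb2.

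The following genes from further down the order were chosen after their values were seen, and no gene class was tested for enrichment among the fullest genes. The heterochromatin protein gene Cbx5 had 3643 sequences, the chromatin regulator gene Ankrd11 3950, the histone H3 methyltransferase gene Nsd1 2976 and the 5-methylcytosine dioxygenase gene Tet3 2742. Trim71, the mammalian homologue of lin-41, had 3148 sequences and the forkhead factor gene Foxo3 had 2667. The share of sequences that began with U differed between genes with many sequences. It was 47.2% for Ankrd11, 50.5% for Spen, 54.4% for Rab11fip4 and 55.3% for Srrm2, against 61.8% for Abl2 and 67.6% for Cbx5. The U content of these transcripts was not measured. Among noncoding genes, 1700001L05Rik had 3286 sequences, Gm10505 2600 and AU020206 2000.

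Within messenger RNAs the sequences came from coding sequence and 3′ UTR, and least from 5′ UTR. On 1 transcript per gene, the 3′ UTR held 51.4% of sequences (51.3–51.5%) on 40.5% of the nucleotides, the coding sequence 45.0% (44.9–45.0%) on 52.4%, and the 5′ UTR 3.64% (3.61–3.66%) on 7.15%. This gave 23.004 distinct ends per kb of 3′ UTR, 17.4 per kb of coding sequence and 10.3 per kb of 5′ UTR. The pooled ratio of 3′ UTR to coding sequence was 1.32 (95% bootstrap interval over genes, 1.27–1.39), whereas the median gene went the other way. Of 4801 genes with 50 or more ends and at least 100 nt in every region, the 3′ UTR was denser than the coding sequence in 2099 (43.7%, 42.3–45.1%). Their median log2 ratio was −0.19. Single genes differed in both directions. The density per nt of 3′ UTR over coding sequence was 2.74 in Foxo3, 2.35 in Trim71, 2.07 in Nsd1, 1.44 in Ccnd2, 1.37 in Gabpb2 and 1.32 in Cbx5, whereas it was 0.478 in Spen and 0.0635 in the splicing factor gene Srrm2. A 5′ U was carried by 72.5% of 3′ UTR sequences, 64.6% of coding sequences and 66.4% of 5′ UTR sequences. The U content of the regions themselves was not measured, so these shares are not set against a background. The transcript with the longest coding sequence was used, and for some genes, Abl2, Ankrd11, Tet3 and Tmem245 among them, it has only 3 nt after the coding sequence, so ends in their other 3′ exons did not enter.

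Gene lists of the piRNA pathway, spermatogonia and meiotic prophase lay above random gene lists matched on transcript length, narrowly so for undifferentiated spermatogonia. Lists of later germ cells and of somatic testis cells lay within the range of theirs, whose lower end was at or near 0. Tdrd9 itself had 137 sense sequences at 96 ends of its 4809-nt transcript (19.96 ends per kb; chromosome 12, 113209842–113307030) and 0 antisense sequences. Because the genotypes are pooled, this value checks no genotype label. All 22 piRNA pathway genes had 10 or more sequences, among them Exd1 with 742, Piwil2 with 452, the helicase gene Mov10l1 with 399 and Tdrkh with 322. Piwil4 (MIWI2) had 28 and Piwil1 (MIWI) 22. The median of this list was 30.5 ends per kb, above 99.9% of 10000 random gene lists of the same size matched on transcript length. Markers of undifferentiated spermatogonia had a median of 24.96, above 97.53% of their random lists, with 13 of 14 genes at 10 or more sequences. Lin28a had 796, Zbtb16 (PLZF) 590 and Sall4 572. Markers of differentiating spermatogonia had a median of 67.5 ends per kb with 9 of 9 genes, including Ccnd2 with 1320, Kit with 223 and Stra8 with 211. Genes of meiotic prophase had a median of 40.3 with 18 of 18 genes, including Tex15 with 1196, the cohesin gene Stag3 with 392 and the synaptonemal complex gene Sycp3 with 199. Both of these lists lay above all of their random lists.

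The list of late spermatocyte and spermatid genes had a median of 3.99 ends per kb, within the 95% range of its random lists (0 to 14.9, median 1.26) and above 75.4% of them, and 5 of 13 genes reached 10 sequences. Ldhc had 49, Tnp1 23, and the protamine genes Prm1 and Prm2 had 0 sense sequences each, as had Tnp2 and Acrv1. Sertoli cell markers had a median of 2.44 ends per kb (above 25.6% of random lists), with 6 of 14 genes at 10 or more. Ctsl held 113 of the 231 sequences of that list, and Sox9 had 27. The Leydig cell list had a median of 0: Star, which imports cholesterol into mitochondria, held 247 of its 254 sequences, and 5 of its 8 genes had none. Peritubular myoid markers had a median of 1.01 (above 15.4%), and markers of endothelium, blood and macrophages 0.275 (above 6.90%). Imprinted genes had a median of 6.29 (above 30.7%), with Peg3 at 353 and Rasgrf1 at 39, and the imprinted noncoding RNAs Kcnq1ot1, H19, Meg3 and Airn had 323, 169, 48 and 5. The medians of the Sertoli, Leydig, myoid, endothelial and imprinted lists all lay within the 95% range of their random lists. For the Leydig, myoid and endothelial lists that range began at 0, so no median could have fallen below it. The Leydig median equalled or exceeded 3.32% of its random lists.

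Ribosomal protein and histone genes, which have short transcripts, also contributed sequences, with a lower share of 5′ U than the germ cell lists. Ribosomal protein genes had a median of 15.03 ends per kb, with 63 of 85 genes at 10 or more sequences. Histone genes, linker histones included, had a median of 19.4, with 49 of 67 genes. Both lists lay above all of their random lists, whose medians were themselves centred on 0 (95% ranges 0 to 2.35 and 0 to 0), so the comparison separates them only from short genes with few or no sequences. Rps3 had 500 sequences and Rpl8 396, and the linker histone gene Hist1h1a had 755. A 5′ U was carried by 52.9% of the ribosomal protein sequences (51.6–54.3%) and 47.2% of the histone sequences (45.6–48.7%), against 69.7% (68.2–71.1%) for piRNA pathway genes and 66.5% (65.004–67.9%) for meiotic genes. The U content of the transcripts in these lists was not measured. Of the ribosomal protein sequences, 96.0% (95.5–96.6%) lay on the chromosome of the gene and the rest on other chromosomes, where processed copies can lie. Rpl23 was the lowest among the 20 fullest ribosomal protein genes, at 52.7%, and was chosen after its value was seen.

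Opposite-strand pairs with the 10-nt overlap left by slicing were in excess but involved few ends. There were 7538 pairs of 5′ ends overlapping by 10 nt, against a mean of 5497 over the other overlaps of 1 to 20 nt (3581 to 7132), a ratio of 1.37 (z = 3.13 over the other overlaps). The next highest overlap was 5 nt, with 7132 pairs. The ratio was 1.37 ± 0.0830 (SD over 19 autosomes), with the lowest autosome at 1.22, and 1.11 on the X chromosome. An end with a 10-nt partner made up 0.436% (0.430–0.443%) of all ends, against 0.318% on average for the other overlaps. Ends antisense to protein-coding genes had such a partner in 4.71% of cases (4.57–4.86%) and ends sense to protein-coding genes in 0.340% (0.331–0.349%). The same ends had a partner at the other overlaps in 3.43% and 0.251% of cases, so their ratios were 1.38 and 1.35. Ends with 4 or more sequences had a ratio of 1.99 and carried a 5′ U in 89.2% of cases. No excess of 5′ ends directly after a 3′ end, the mark of stepwise cleavage, was detectable: the ratio of distance 1 to distances 2 to 20 was 1.01 (z = 0.826). Each distinct end was counted once, with 200612 pairs at distance 1 against a mean of 198253. Cleavage followed by shortening of the 3′ end would be missed. The count therefore does not show that stepwise cleavage was absent.

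**Figure D2:**
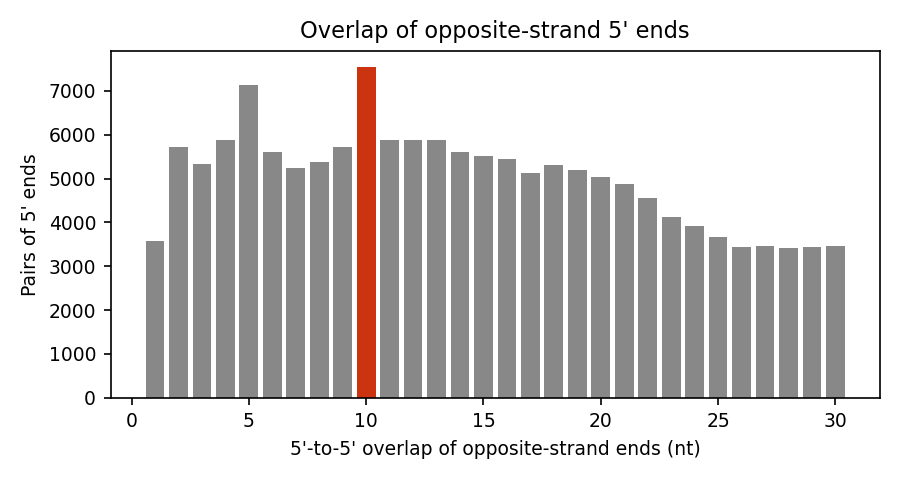
Pairs of distinct 5′ ends on opposite strands (vertical axis, number) by the length of their 5′-to-5′ overlap (horizontal axis, nt), 4 libraries pooled. The bar at 10 nt holds 7538 pairs, and the next highest, at 5 nt, holds 7132.

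Ends from recurring sequence had A at position 10 more often than ends found at a single position. Their share with a 10-nt partner was no higher, but other overlaps were rarer, so their 10-nt ratio was higher. Partners were sought at the listed position only, so any missing from the list because they match several genome positions could not be counted. The 29129 ends whose first 20 nt occurred at 2 or more listed positions had A at position 10 in 47.9% of cases (47.4–48.5%), and the 3070 ends whose first 20 nt occurred at 10 or more positions in 60.8% (59.1–62.5%), against 31.4% (31.4–31.5%) for ends found at a single position. A 10-nt partner was present for 0.367% (0.301–0.444%), 0.456% (0.250–0.764%, 14 ends) and 0.437% (0.430–0.444%) of the ends in these sets. The other overlaps were rarer in the recurring sets, at 0.0903% and 0.0291% on average against 0.320%, which gave 10-nt ratios of 4.07, 15.6 and 1.36. A 5′ U was carried by 80.1% (78.6–81.5%) of the ends at 10 or more positions. These ends belong to 168 different 20-mers, which lie on 21 chromosomes.

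**Figure D3:**
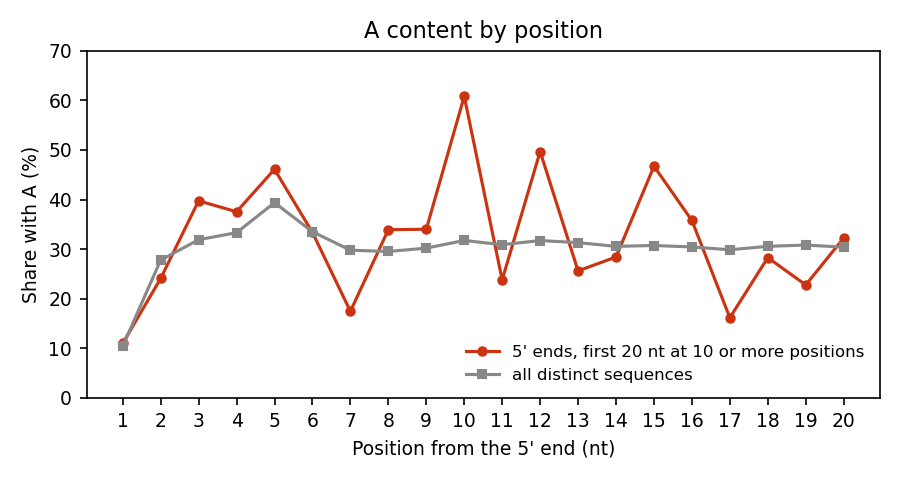
Share of A (vertical axis, percent) at positions 1 to 20 from the 5′ end (horizontal axis, nt) for the 3070 ends whose first 20 nt recur at 10 or more positions (circles) and for all distinct sequences (squares). The first curve reaches 60.8% at position 10 and 49.7% at its next highest position, and the second stands at 31.7% at position 10.

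Dense genomic windows held 20.3% of the list, and most of them carried sequences mainly on a single strand. Of 81833 windows of 20 kb with a sequence, 581 held 1000 or more, whereas the median window held 8. They formed 510 clusters, of which the 10 fullest held 2.64% of the list. In 466 of the 581 (80.2%), at least 90% of the sequences lay on 1 strand. Over 90% of the sequences were sense to a protein-coding gene in 236 of these windows, and under 10% were sense to any transcript in 75. The fullest cluster, on chromosome 17 from 27420001 to 27520000 (mm9), held 33985 sequences, 58.5% of them on the plus strand. Its minus-strand sequences lay to the left of the plus-strand ones, which ran through the noncoding genes Gm10505 and Gm49794. It also held the 3 fullest single windows of the genome, with 11076, 8454 and 8340 sequences. The next clusters were D10Wsu102e on chromosome 10 (82820001–82960000, 19234 sequences, 99.8% plus) and chromosome 7 from 6520001 to 6620000 (17004 sequences, 0.0588% plus, 524 of them sense to Zim2). Chromosome 2 from 92380001 to 92440000 held 10910 sequences (99.3% plus, 1.0999% sense to a transcript), and chromosome 9 from 67540001 to 67600000 held 10256 (21.8% plus, 0.0488% sense to a transcript). The other windows among the 5 fullest were chromosome 1 from 133920001 to 133940000, with 5940 sequences of which 2207 were sense to Elk4, and chromosome 7 from 6580001 to 6600000, with 5793.

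**Figure D4:**
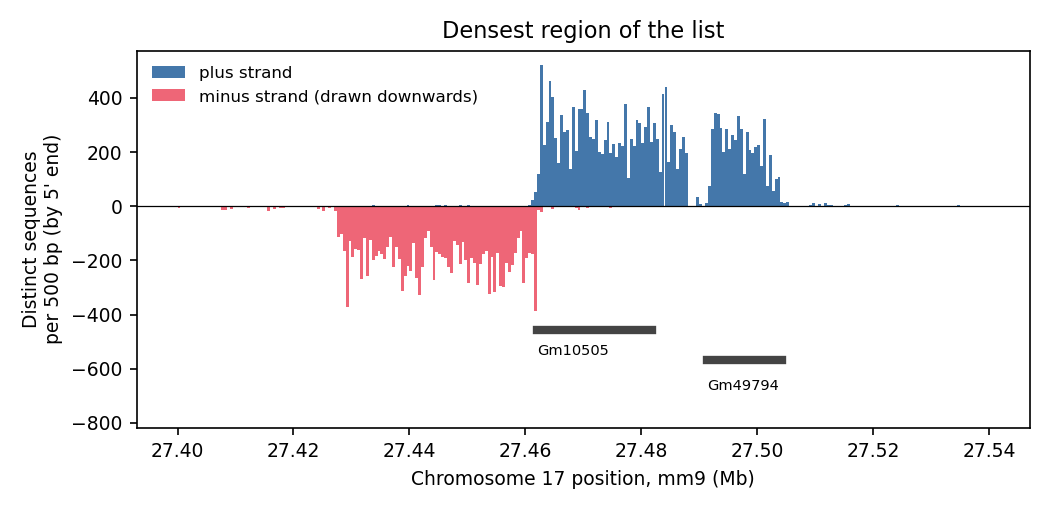
Distinct sequences per 500 bp by 5′ end (vertical axis, number; plus strand upwards, minus strand downwards) along chromosome 17 in mm9 (horizontal axis, Mb), with the spans of the sequences of Gm10505 and Gm49794 as dark bars. The cluster holds 33985 sequences, 58.5% of them on the plus strand, with the minus-strand block to the left of the plus-strand blocks.

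Autosomes and sex chromosomes differed in density. Autosomes held 1973 sequences per Mb on average (SD 647 over 19 autosomes), from 1089 on chromosome 3 to 3626 on chromosome 11. The X chromosome held 516 per Mb, 0.262 of the autosome mean and below the lowest autosome. Each chromosome's length was taken as its last listed position. The Y chromosome held 1018 sequences, all within its first 2902546 positions, and the mitochondrial genome held 163. X-linked genes with many sequences included the ubiquitin ligase gene Rlim with 1043 and Tmem164 with 989.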

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

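Of the 37 alternatives run on 9 results, 16 were planned and the others were chosen after seeing the data: 1 value per 5′ end, pairs weighted by sequences, ends with 2 or more sequences, recurring ends left out, 10 and 50 kb windows, other transcripts or gene rules, and the fullest genes left out. Only the pooled ratio of 3′ UTR to coding sequence was checked for a turn of direction, and it stayed above 1 in its alternatives. The comparison per gene, whose median went the other way, was not among them. Over all alternatives, 19 values stayed within the interval of the reported value or, for the count of genes, within 1.5 times it. The other 18 fell outside. Intervals of shares cover counting error only, that of the 10-nt ratio is its SD over autosomes and that of the UTR ratio a bootstrap over genes. Counting each 5′ end once gave 72.0% with a 5′ U, 31.5525% with A at position 10, a mean length of 27.1277 nt, a sense share of 93.6%, a structural RNA and microRNA share of 0.0700% and 19.7% of the list in the fullest 1% of windows (24.7% as reported). Ends with 2 or more sequences gave 82.7% with a 5′ U, 32.1% with A at position 10 and a 10-nt ratio of 1.72, and weighting pairs by sequences gave 1.56. Without recurring ends 75.3905% had a 5′ U and 31.5991% A at position 10. Sequences of 24 to 31 nt gave a mean length of 27.159 nt, a structural RNA and microRNA share of 0.0822% and 24.6% in the fullest windows. Windows of 10 kb gave 27.3% and of 50 kb 20.5%. Without the 100 fullest genes the ratio of 3′ UTR to coding sequence was 1.21. Causes of these moves were not tested, beyond what each setting leaves out. The count of protein-coding genes with 100 or more sequences ranged from 4111 to 5849. All 12 gene lists kept their side of the random range with only sequences on the gene's own chromosome. That setting could change little: at least 96.0% of the sequences of each list stayed, and every list median was unchanged. No paired analysis was possible because the pooled table has no library column. For the same reason the planned scalings, count filters, leaving out each library, other count tests and repeat annotations were not run. Read depth is unknown and limits every density here, since each sequence counts once.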

Other observations

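The tests of the X chromosome on sequences without a transcript match and on genes with a sequence were chosen only after the result was seen, as were the genes and regions of the next paragraphs. The genes with the most antisense sequences included several with few sense ones. Mfsd4a had 1819 antisense and 149 sense sequences, Ank3 1249 and 171, Mroh2a 883 and 11, and the testis kinase gene Tssk1 447 and 27. Star, the main gene of the Leydig list, had 105 antisense beside 247 sense sequences. Among pseudogenes, the processed copy Gm18609 had 1077 antisense and 0 sense sequences of its own, Gm18009 374 and 0, and Plk-ps1 345 and 0. Some noncoding and structural RNA genes had few sequences with a 5′ U. The gene Gm42418, annotated as a lincRNA, had 1136 sequences on the plus strand of chromosome 17 from 39983975 to 39985681, with 27.6% 5′ U. Its span lies within that of the sequences of the ribosomal RNA gene CT010467.1 (39983411–39985692, minus strand, 31.6% 5′ U). By its annotation Gm42418 was counted among noncoding genes, so its sequences are not in the structural RNA share. The 7SK RNA gene Rn7sk had 116 sequences with 30.2% 5′ U, and the mitochondrial ribosomal RNA mt-Rnr2 had 50 with 16%, whereas the small nuclear RNA gene Rnu11 had 71 with 49.3% and the Y RNA gene Rny3 63 with 49.2%.

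Clusters with both strands fell into separate arrangements. Of 117 clusters with 10 to 90% of sequences on the plus strand, 55 had the minus-strand sequences to the left (divergent) and 62 to the right (convergent). All 10 of those with under 10% of sequences sense to a transcript were divergent (lower exact bound 69.2%), including chromosome 9 from 67540001 to 67600000 and chromosome 12 from 99620001 to 99680000. Of the other 107, 45 were divergent (42.1%, 32.6–52.0%). Other positions were uneven too: G stood at position 2 in 44.8% of sequences with a 5′ U and 25.2% of those without, and A at position 5 in 40.04% and 37.3%. Of 315 sequences of 35 or 36 nt, 115 began with 10 or more A.

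Ends whose first 20 nt recur at 10 or more positions had A at position 10 in 60.8% of cases. Repeats rich in A throughout are argued against as the cause, because A at position 10 exceeded the next highest position of the same ends by 11.1 percentage points. A few very frequent 20-mers are argued against as well: with each of the 168 counted once, A at position 10 stood at 59.5% (51.7–67.02%) and the excess was 11.3 points. Related 20-mers of the same repeat family were not grouped, and the interval treats all 168 as independent. A few families that carry A at that position therefore stay open. The requirement for a single genome position, which keeps only copies that differ within the read, was not tested and stays open. The design names only the genotype, which is pooled here, so no biological explanation was tested for this pattern.

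The X chromosome held 0.262 of the autosome mean per Mb. Loss by unique mapping of repeated sequence outside exons is argued against as the whole cause. X transcripts had 10.8 ends per kb (bootstrap 9.40–12.2) against 14.2 on the lowest autosome, and 14.1 (12.5–15.95) against 18.8 among genes with a sequence. How much exon sequence has a single genome match was not measured, so loss from exons of duplicated genes stays open. A single X beside a pair of each autosome may account for the transcript part, where the X to autosome ratio was 0.537 (0.467–0.613) and its interval held 0.5. Distinct ends rise only up to a ceiling, so a single copy need not give 0.5. Fewer X genes than autosomal genes also had a sequence (61.7% against 72.3%), so the ratio cannot single out copy number. A single X is too small a difference for the sequences without a transcript match, whose ratio was 0.257 (0.196–0.328). For those, loss by unique mapping stays open too, and beyond copy number no biological explanation was tested.

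A 5′ U was less frequent in sequences sense to protein-coding genes (69.2%) than in unmatched ones (81.6%). Fragments of messenger RNA not bound by MILI may contribute: the gap was 21.3 percentage points at ends with a single sequence (odds ratio 2.68), 13.5 at ends with 2 or 3 (odds ratio 2.44) and 2.99 at ends with 4 or more (odds ratio 1.39), just under the bound of 3 points set before that gap was seen. The drop in odds ratio rests mainly on the last class, where both shares (88.3% and 91.3%) are near their ceiling. A ceiling on distinct sequences at U positions of dense genes stays open. Counted per 5′ end, the share was 62.9% at ends sense to protein-coding genes and 79.5% at unmatched ends. From the sparsest to the densest of 4 equal groups of genes it was 77.5% (77.0–78.1%), 70.5%, 65.7% and 60.8%. The 77.5% lies between the 80% set for that explanation and the 75% set against it. The 80% bound exceeds the share of the unmatched ends themselves, so it cannot decide the question. The U content of the source sequence was not measured in either set, so the gap is not set against a background. No biological explanation was tested.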
